A study of Homo sapiens with 6 samples.

How the data were processed

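Expression was measured by strand-specific sequencing of total RNA from 6 samples of SW480, a human colon cancer cell line. The labels put 3 samples in an ALDH1B1 knockdown group and 3 in a control group, each numbered 4, 5 and 6. The extraction notes mention detachment of the cells with trypsin. How the knockdown was made, and whether ribosomal RNA was removed, are not given in the sources used here.

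The deposited table holds, for each gene and sample, the log2 of RPM (reads scaled to a fixed sequencing depth) plus an offset of 1e-04, a scale read from the values because the authors' labels do not state it. Every column had its floor at that offset. After the log and the offset were undone, most low values of each column were multiples of a single step, taken here as the value of 1 read. From that step, the depth used for scaling was about 28580000, 21090000 and 23540000 reads for control replicates 4, 5 and 6, and 21060000, 20360000 and 26160000 reads for knockdown replicates 4, 5 and 6. The listed genes held 65.1% to 71.1% of it, so it includes reads that no listed gene carries. The submitters name Partek and Bowtie, without versions, and the build hg38. The positions in the table are not those of GRCh38, since the largest end on chromosome 1 was 249214146 against 248937043 for the last gene in GENCODE 29. Positions are therefore given as the table has them, and the table's build, gene models, counting method and filters are not given in the sources used here.

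The table has 24549 lines and 22258 gene symbols. A symbol placed at several loci, which applied to 1192 symbols, had identical values at each, and was used once. Between 75.4% and 76.3% of low values lay within 0.02 reads of a whole number, and 62.5% to 65.6% of higher ones, so the values are not plain counts and count models were not run.

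The 15496 genes with a mean of at least 0.688 RPM were tested. The test was limma (R 4.3.3, limma 3.58.1, statmod 1.5.0), with lmFit and eBayes with a trend on the deposited log2 values, knockdown against control, with 3 samples per group and no covariates. It was two-sided, with Benjamini-Hochberg adjustment over all genes tested and an adjusted p threshold of 0.05. The words rose and fell are used only for genes past it. Group means are given in RPM with the SD over 3 samples, and log2 fold changes with limma's standard error. ALDH1B1 was also tested with an exact two-sided permutation test of its 6 values. The level of 3 reads, taken as the floor, was 0.105 to 0.147 RPM. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

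The comparison, the test, the gene lists, the alternatives named in the closing section as planned and the rule for naming genes were fixed before the data were examined. The rule names ALDH1B1, then the 12 largest rises and the 12 largest falls in log2 fold change among genes that passed the test, had a mean of at least 3.44 RPM and had no overlap between groups. Non-coding and unnamed loci were left out by their symbols. For each gene list with a changed member it allows up to 4 members with the smallest adjusted p, for the ALDH family any tested member, and for lists of other cell types and of RNA quality the most abundant members. Of the lists tested, 1 that did not pass is left out of the text, as are some members of other lists that the rule allows. VIM, MYC, CTGF, EGR1, ZEB1, ACTA2, COL6A1, MMP9, NPM1, MT-RNR1, MT-RNR2 and the mitochondrial transcripts outside that rule were named after their values were seen.

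Of 42 gene lists, 39 had at least 5 tested members and were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 39 lists, including the list left out of the text. Of 1601 list members, 1361 were matched by symbol, 72 by an older symbol and 168 not at all. The lists described in the text covered the ALDH family, retinoid metabolism, alcohol and aldehyde clearance, Wnt/beta-catenin targets, the Notch pathway, stem cell markers, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones and DNA repair. They also covered nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the TCA cycle, the mitochondrial and cytosolic ribosome, MYC targets and ribosome biogenesis, glycolysis and hypoxia, NRF2 targets, the ATF4 response, the unfolded protein response, heat shock, cholesterol, fatty acid, and folate and serine metabolism. The others were epithelial and mesenchymal genes, TGF-beta and YAP targets, MAPK output and immediate early genes, interferon, NF-kB and cytokines, intestinal differentiation, drug transport and metabolism, apoptosis, extracellular matrix and integrins, RNA interference machinery, small nucleolar and small nuclear RNA, nuclear long non-coding RNA, and markers of fibroblasts, leukocytes, endothelium and blood, and kidney, liver and breast lines. Beside camera at the preset correlation, camera with an estimated correlation, camera on ranks and fry were run. fry tests whether a list's genes move, on balance, in a single direction, and does not compare the list with other genes.

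Positions were examined in windows of 10 Mb over 15469 genes placed at a single locus. Windows were chosen on every second gene in order of position, where at least 10 such genes had a median log2 fold change at least 0.2 above that of all placed genes, and were then measured on the genes held out. They are called shifted windows here. GC content came from GENCODE 29 transcripts for 14023 tested genes. Random lists matched on expression (10 bins) and GC content (5 bins) were drawn 10000 times per list.

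Alternatives covered the pseudocount, the low-value filter, rescaling of the columns, quantile normalization, the variance prior, array weights, a replicate block, a stricter threshold, a minimum fold, other list tests, leaving out each sample, GC correction and removal of position effects. Rescaling by trimmed means and count models were planned and were not run. The fit was tested on 5 sets of simulated counts of the same depth with 200 changed genes each and an assumed dispersion of 0.005, a value not estimated from these samples. It recovered 34.65% of changes of 1.25-fold, 80.5% of changes of 1.5-fold and 95.9% of changes of 2-fold, with 4.41% of calls false. A list of 50 genes shifted by 0.2 was called in 5 of 5 simulations, and 0 of 95 unshifted lists were called. The simulated genes were drawn independently of each other, so these runs cannot show how list calls behave when genes are correlated.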

Results

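SW480 is a colon cancer line with truncated APC. ALDH1B1 is a mitochondrial aldehyde dehydrogenase that oxidises acetaldehyde, lipid aldehydes and retinal. The series asks what role ALDH1B1 has in these cells, and its samples form a single comparison of 3 ALDH1B1 knockdown samples with 3 control samples. The depth was about 20360000 to 28580000 reads per sample, and 271 to 618 of the listed symbols had no read in a given sample. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

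The knockdown samples had less ALDH1B1 mRNA than the control samples. They had more E-cadherin and several other epithelial transcripts, and less fibronectin and other TGF-beta-responsive transcripts. At a preset correlation between genes, lists for ribosome production, heat shock and the mitochondrial ribosome were lower, while mitochondrial mRNAs and immediate early genes were higher. With an estimated correlation none of these list calls held (adjusted p = 0.988). Part of the rises followed chromosome position.

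ALDH1B1 was lower in every knockdown sample than in every control sample. The gene (chromosome 9, 38392661 to 38398659 in the table's coordinates, whose build is not named) had 36.8 ± 2.76 RPM (reads scaled to sequencing depth) in the control (SD, n = 3) and 21.2 ± 1.74 in the knockdown (SD, n = 3), which is 57.6% of control. Its log2 fold change was -0.80 (SE 0.0926, limma adjusted p = 2.37e-07). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 samples allow. Control replicates 4, 5 and 6 had 34.1, 39.6 and 36.8 RPM, and knockdown replicates 4, 5 and 6 had 19.99, 20.4 and 23.2. These values rest on about 416 to 974 reads per sample. The fall was partial and ranked 307 among all falls in log2 fold change, so a sizeable part of the message remained.

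The knockdown and control transcriptomes differed over a large part of the expressed genes. Of 15496 genes tested, 6480 (41.8%) changed, of which 3508 rose and 2972 fell. Which direction had more genes depended on the scaling and on control replicate 6. Rescaling by median of ratios gave 3683 that rose and 4075 that fell, nuclear protein-coding totals gave 4569 and 2867, and without control replicate 6 there were 3057 and 3738. Most changes were small, with a median absolute log2 fold change of 0.46 among changed genes. A rise of at least 1 log2 unit was found for 725 genes and a fall of that size for 187. The groups did not overlap for 7908 tested genes (51.0%, against 10% by chance) and for 6187 of the changed genes. Correlations across genes between samples of a group were 0.989 to 0.993, and between groups 0.959 to 0.972. The first principal component held 68.5% of the variance and separated the groups, and control replicate 6 lay apart on the second, which held 11.5%. After group means were removed, samples with the same replicate number had correlations across genes of -0.05, -0.06 and -0.13, so the numbers did not pair the samples.

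**Figure D1:**
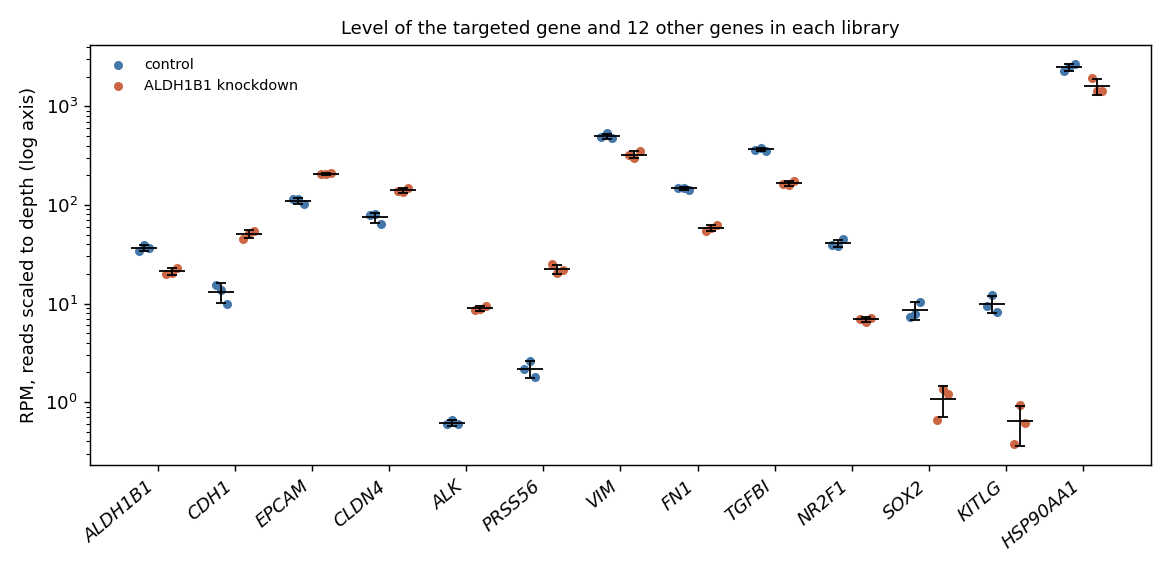
RPM on a log axis for ALDH1B1 and 12 other genes in each of the 3 control and 3 knockdown samples, with black bars for the mean and SD. ALDH1B1 went from 36.8 to 21.2 RPM, CDH1 from 13.1 to 51.0 and KITLG from 10.01 to 0.642.

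The 12 largest rises are given among named genes with a mean of at least 3.44 RPM whose groups did not overlap. ALK, a receptor tyrosine kinase best known as an oncogene in lymphoma, lung cancer and neuroblastoma, rose most of these (chromosome 2, 29415640 to 30144433), from 0.618 ± 0.0400 to 8.97 ± 0.497 RPM, a log2 fold change of 3.86 (SE 0.196, adjusted p = 1.58e-13). EDN3, an endothelin peptide that acts on neural crest and melanocyte precursors, rose by 3.50 on the log2 scale (chromosome 20, 57875482 to 57901048). PRSS56, a secreted serine protease known from eye growth, rose from 2.19 ± 0.412 to 22.4 ± 2.41 RPM, a log2 fold change of 3.37. ANTXR1, a collagen-binding anthrax toxin receptor, rose by 2.96, and CAPN8, a calpain protease of the gastric mucosa, by 2.87. SYT8, a synaptotagmin of regulated secretion, rose by 2.86, and KCNJ10, an inward-rectifier potassium channel of glia and kidney, by 2.79, to 42.6 ± 4.06 RPM. KANK4, a regulator of actin at focal adhesions, rose by 2.63, UROC1, the urocanase of histidine breakdown in liver, by 2.51, and GRIP2, a scaffold for glutamate receptors, by 2.43. RGPD2 and RGPD3, primate copies of the nuclear pore gene RANBP2, rose by 2.55 and 2.47, but the copies are near identical and may share reads. Of these 12 genes, 5 (ALK, ANTXR1, RGPD2, RGPD3 and GRIP2) lay in shifted windows, where neighbouring genes were also higher. Among all placed genes that rose by at least 1 log2 unit, 27.8% lay in such windows.

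None of the 12 largest falls under the same rule lay in a shifted window. Those windows were chosen for higher genes, and 3.52% of the genes in them fell, so this was likely from the outset. Whether these 12 genes lay in windows chosen for lower genes was not examined. KITLG, the ligand of the KIT receptor, fell most of these (chromosome 12, 88886570 to 88974629), from 10.01 ± 2.04 to 0.642 ± 0.278 RPM, a log2 fold change of -4.04 (SE 0.251, adjusted p = 5.49e-12). CTHRC1, a secreted collagen triple helix protein linked to cell migration, changed by -3.51, and SOX2, a pluripotency factor used as a marker of stem-like cancer cells, by -3.02, from 8.52 ± 1.73 to 1.09 ± 0.374 RPM. KCNMA1, the large-conductance calcium-activated potassium channel, changed by -2.98. TLE1, a Groucho co-repressor that restrains Wnt and Notch target genes, changed by -2.82, and TGFB2, a TGF-beta ligand, by -2.79. GGT5, which cleaves glutathione conjugates and leukotrienes, changed by -2.75, and SEMA3A, a semaphorin that guides axons and vessels, by -2.57. NR2F1, an orphan nuclear receptor tied to development and tumour dormancy (chromosome 5, 92919043 to 92930322), went from 40.8 ± 3.64 to 6.90 ± 0.370 RPM, a log2 fold change of -2.56 with the joint smallest adjusted p among these falls, 2.33e-15. KRT81, a hair keratin, shared that p with a change of -2.22. CXCL14, an epithelial chemokine, changed by -2.23, and SYTL2, an effector of vesicle transport, by -2.07.

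Of the 39 gene lists tested, 4 were higher and 7 lower in the knockdown at the preset correlation. With an estimated correlation camera called 0 of them, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.988. Every camera call therefore rests on the preset value, and the estimated setting does not tell the lists apart. Of the 11 lists, fry, which takes no preset correlation, called 5 in the same direction (mitochondrially encoded genes, the mitochondrial ribosome, MYC targets and ribosome biogenesis, heat shock, and TGF-beta and YAP targets).

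**Figure D2:**
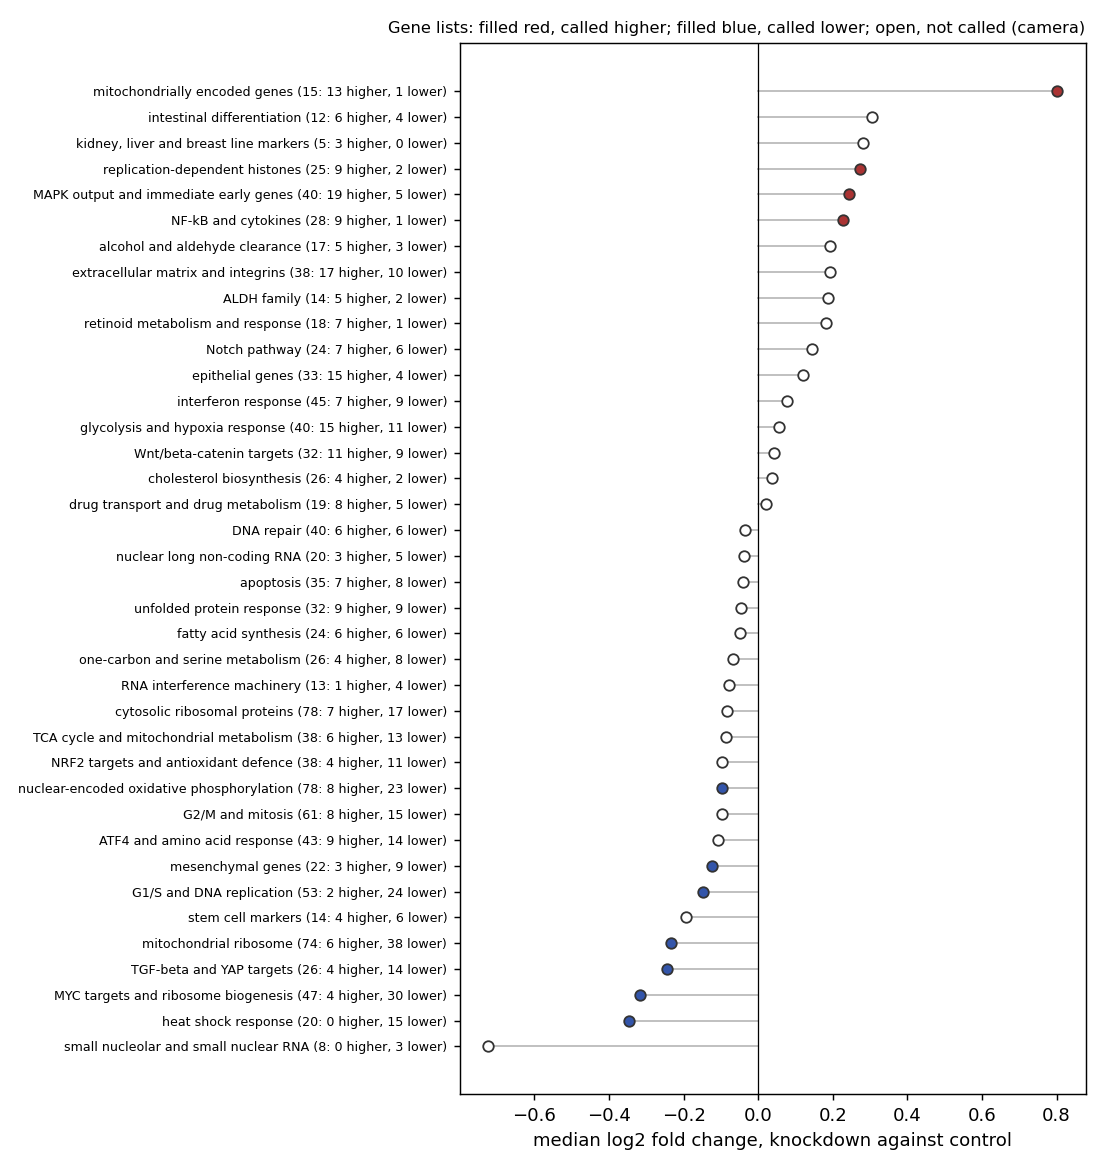
Median log2 fold change of 38 of the tested gene lists, knockdown against control, with the number of tested members and of members that rose and fell after each name. Filled points passed camera at the preset correlation, and mitochondrially encoded genes had the highest median at 0.80.

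The mesenchymal list and the TGF-beta and YAP list were lower at the preset correlation, and several epithelial genes were higher. The TGF-beta and YAP list fell (adjusted p = 0.00115, and 0.988 with an estimated correlation), with 14 of 26 members that fell and 4 that rose (14 and 5 adjusted over the list alone). TGFBI, a matrix protein induced by TGF-beta (chromosome 5, 135364584 to 135399508), went from 366 ± 11.6 to 165.2 ± 9.19 RPM, a log2 fold change of -1.15 (SE 0.0733, adjusted p = 8.14e-12). NT5E, the ectonucleotidase that makes adenosine, changed by -1.41, and the YAP targets CYR61 and CTGF by -0.98 and -1.01. The mesenchymal list was lower (adjusted p = 0.01999, and 0.988 with an estimated correlation), with 9 of 22 members that fell and 3 that rose, the same numbers as when adjusted over the list alone. Fibronectin, FN1 (chromosome 2, 216225163 to 216300896), went from 147.2 ± 4.18 to 58.1 ± 4.196 RPM, a log2 fold change of -1.34. Tropomyosin TPM1 changed by -1.07, the repressor SNAI2, which silences E-cadherin, by -2.93, the intermediate filament VIM by -0.63 and the repressor ZEB1 by -0.60. SNAI2 went from 2.62 ± 0.471 to 0.349 ± 0.0915 RPM, not far above the floor. The 3 that rose were ACTA2, COL6A1, in a shifted window, and MMP9, by 1.08, 0.39 and 1.33. The mesenchymal call was lost with camera on ranks, without a variance trend and under quantile normalization. The list's median lay inside the range of random lists matched on expression and GC content.

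The cadherin of epithelial junctions, CDH1 (chromosome 16, 68771128 to 68869452), rose from 13.1 ± 2.92 to 51.0 ± 4.97 RPM, a log2 fold change of 1.98 (SE 0.122, adjusted p = 3.93e-12). EPCAM, an epithelial adhesion molecule, rose by 0.90, the tight-junction claudin CLDN4 by 0.92 and the epithelial transcription factor ELF3 by 0.87, of which EPCAM and CLDN4 lay in shifted windows. Of 33 epithelial genes, 15 rose and 4 fell, also when adjusted over the list alone, but the list missed the threshold (adjusted p = 0.0530). Matrix and integrin genes went both ways. The adhesion-modulating matrix protein tenascin, TNC, fell from 45.7 ± 2.02 to 11.4 ± 1.24 RPM, a log2 fold change of -2.01, and the metalloproteinase inhibitor TIMP3 changed by -1.53. ITGB8, an integrin that activates latent TGF-beta, rose by 1.75. In that list 17 of 38 members rose and 10 fell (18 and 10 adjusted over the list alone, adjusted p = 0.245). Intestinal genes were also split, with 6 of 12 that rose and 4 that fell, also when adjusted over the list alone (adjusted p = 0.788). VIL1, the villin of the brush border, rose by 1.90 and EPS8L3, of the EPS8 family of actin regulators, by 1.80, while the gut transcription factors KLF4 and CDX2 changed by -0.92 and -0.76.

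Genes for making ribosomes were lower. The list of MYC targets and ribosome biogenesis fell (adjusted p = 2.74e-07, and 0.988 with an estimated correlation), with 30 of 47 members that fell and 4 that rose (32 and 4 adjusted over the list alone). Outside the shifted windows 29 members fell and 0 rose, but those windows were chosen for higher genes, so leaving them out takes away rises. UTP20, a factor of small-subunit processing (chromosome 12, 101673887 to 101780395), went from 64.5 ± 4.89 to 39.6 ± 0.420 RPM, a log2 fold change of -0.70 (SE 0.0811, adjusted p = 2.14e-07). The nucleolar helicase DDX21 changed by -0.62, the export factor RRP12 by -0.53, the nucleolar chaperone NOLC1 by -0.47 and nucleophosmin NPM1 by -0.41. MYC itself, the transcription factor that drives many of these genes, changed by -0.47 (adjusted p = 2.34e-05). Cytosolic ribosomal proteins did not pass as a list (adjusted p = 0.0835), with 7 of 78 that rose and 17 that fell (6 and 9 adjusted over the list alone). Their smallest p belonged to RPL32, RPL15, RPL31 and RPS7, which rose by 0.54 to 0.59, and of these RPL32, RPL31 and RPS7 lay in shifted windows. RPL15 lay between shifted windows on chromosome 3, in a window with too few genes to be chosen. There 8 of 15 genes rose and 0 fell, with a median log2 fold change of 0.35.

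Heat shock genes, most of them chaperones, fell as a list (adjusted p = 1.47e-06, and 0.988 with an estimated correlation), with 15 of 20 members that fell and 0 that rose, also when adjusted over the list alone. HSP90AA1, the inducible HSP90 and the most abundant of the members named here, went from 2490 ± 211 to 1589 ± 290 RPM (SD, n = 3 each), a log2 fold change of -0.66 by limma. Its co-chaperone STIP1 changed by -0.54, HSPH1 of the HSP110 family by -0.56, and the collagen chaperone SERPINH1 by -0.50. The unfolded protein response list, with genes of the endoplasmic reticulum, had 9 members of 32 that rose and 9 that fell (9 and 10 adjusted over the list alone, adjusted p = 0.826), and the list's median was -0.05 while its mean was 0.04. SSR3, of the translocon, changed by -0.64, whereas the mannosidase-like EDEM1, CRELD1 and the disulfide isomerase PDIA4 rose by 0.81, 1.27 and 0.45, and these rises lay in shifted windows.

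The 13 mRNAs encoded by the mitochondrial genome were higher. At the preset correlation the lists of mitochondrial ribosomal proteins and of nuclear-encoded oxidative phosphorylation were lower. The mitochondrial list was higher (adjusted p = 2.74e-07, and 0.988 with an estimated correlation), with 13 of 15 members that rose and 1 that fell (13 and 2 adjusted over the list alone). The 13 that rose were the 13 mRNAs, by 0.35 (MT-ND5) to 1.04 (MT-ND3). MT-CO1 and MT-ND5 did not keep this direction under quantile normalization, where they had log2 fold changes of 0 and -0.03. The mRNAs took 3.86% ± 0.395 of reads in the control and 6.38% ± 0.0455 in the knockdown (SD, n = 3). MT-ND3 and MT-ND4L, subunits of complex I, rose to 803 ± 33.8 and 670.5 ± 12.4 RPM, MT-ATP8 of the ATP synthase rose by 0.90 and MT-ND1 by 0.86. The ribosomal RNA MT-RNR1 fell by 1.07 on the log2 scale, with 2218 ± 1068 RPM in the control, a call lost with the robust or the untrended variance prior, and MT-RNR2 had a log2 fold change of -0.23 (adjusted p = 0.0713), which passed under 6 alternatives.

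**Figure D3:**
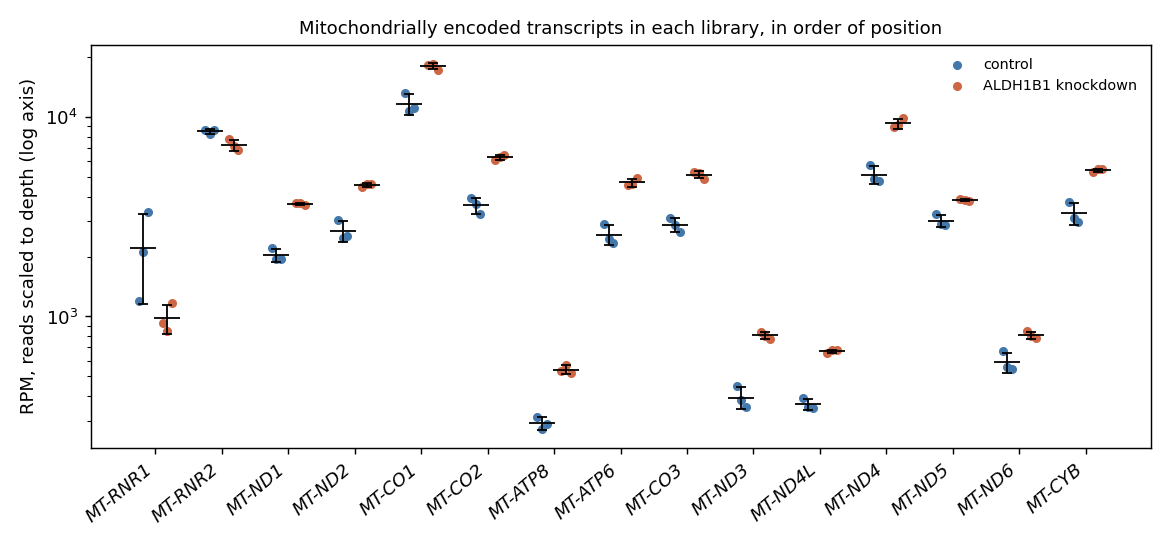
RPM on a log axis for the 15 mitochondrially encoded transcripts in each of the 3 control and 3 knockdown samples, in order of position, with black bars for the mean and SD. The 13 mRNAs were higher in the knockdown, while MT-RNR1 went from 2218 to 981.5 RPM; under quantile normalization MT-CO1 and MT-ND5 had log2 fold changes of 0 and -0.03.

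The list of mitochondrial ribosomal proteins fell (adjusted p = 3.81e-05, and 0.988 with an estimated correlation), with 38 of 74 members that fell and 6 that rose (39 and 7 adjusted over the list alone). All 6 that rose lay in shifted windows, among them the small-subunit protein MRPS25 with 0.88, and outside those windows 38 fell and 0 rose. Here too, leaving out windows chosen for higher genes takes away rises. MRPL18, a large-subunit protein that also brings 5S ribosomal RNA into mitochondria, went from 41.0 ± 1.81 to 24.3 ± 1.962 RPM, a log2 fold change of -0.76, and MRPS30 and MRPL47 changed by -0.56 and -0.60. Nuclear-encoded oxidative phosphorylation was lower by less (adjusted p = 0.0272, and 0.988 with an estimated correlation), with 23 of 78 that fell and 8 that rose (23 and 7 adjusted over the list alone). The complex I subunit NDUFB9 changed by -0.46, and UQCRC2 and CYC1 of complex III by -0.45 and -0.42, while NDUFB2, in a shifted window, rose by 0.54. This call was lost without knockdown replicate 5 or 6 (adjusted p = 0.0841 and 0.0871), with a stricter filter and under quantile normalization, and the list's median lay inside the range of random lists matched on expression and GC content. In the TCA cycle list 13 of 38 fell and 6 rose, also when adjusted over the list alone (adjusted p = 0.245), among them the oxoglutarate dehydrogenase subunit DLST with -0.48, the mitochondrial pyruvate carrier MPC1 with -0.66 and the isocitrate dehydrogenase subunit IDH3B with -0.38. The succinyl-CoA ligase subunit SUCLG1, in a shifted window, rose by 0.43.

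Replication genes were slightly lower, by no more than the range of random lists matched on expression and GC content. The G1/S and DNA replication list was lower (adjusted p = 0.00115, and 0.988 with an estimated correlation), with 24 of 53 members that fell and 2 that rose, also when adjusted over the list alone. MCM2, a subunit of the replicative helicase, and MCM10, which acts in its activation, changed by -0.39 and -0.53, and thymidylate synthase TYMS, the target of fluorouracil, by -0.44. The ribonucleotide reductase subunit RRM2 rose by 0.50, in a shifted window. The mitosis list missed the threshold (adjusted p = 0.0530), with 15 of 61 that fell and 8 that rose (14 and 8 adjusted over the list alone). The cell cycle transcription factor MYBL2 changed by -0.61, the anaphase activator CDC20 by -0.53, the kinesin KIF20A by -0.48 and cyclin CCNA2 by -0.43. Replication-dependent histones were higher as a list (adjusted p = 0.0283, and 0.988 with an estimated correlation), with 9 of 25 that rose and 2 that fell (10 and 2 adjusted over the list alone). HIST1H1C, HIST1H2AC, HIST2H2BE and HIST1H2BK rose by 0.71 to 0.9995 on the log2 scale. That call was lost without control replicate 4 (adjusted p = 0.454), with camera on ranks and under 4 processing alternatives, namely no low-value filter, quantile normalization, removal of window medians and rescaling to nuclear protein-coding totals, and its median too lay inside the range of matched lists.

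At the preset correlation the lists of MAPK output and immediate early genes and of NF-kB and cytokines were higher, while the interferon list was not. The list of MAPK output and immediate early genes rose (adjusted p = 0.00317, and 0.988 with an estimated correlation), with 19 of 40 members that rose and 5 that fell (21 and 5 adjusted over the list alone). Immediate early genes also follow cell handling, and a difference in handling between the groups was not tested. NR4A1, an orphan nuclear receptor induced within minutes of stimulation (chromosome 12, 52416616 to 52453292), rose from 26.3 ± 4.47 to 71.8 ± 5.28 RPM, a log2 fold change of 1.46 (SE 0.102, adjusted p = 4.26e-11). FOSB, an AP-1 subunit, rose by 0.92, EGR1, an immediate early zinc finger factor, by 0.88, KLF10, a TGF-beta-inducible repressor, by 0.80, and the EGFR ligand TGFA, in a shifted window, by 0.93. The list of NF-kB and cytokines was higher (adjusted p = 0.0283, and 0.988 with an estimated correlation), with 9 of 28 that rose and 1 that fell, also when adjusted over the list alone. TNFAIP2, a TNF-induced gene, rose by 0.77, the IL-6 family cytokines LIF and IL11 by 0.81 and 1.76, and TNF by 1.36, from 1.31 ± 0.0171 to 3.37 ± 0.0835 RPM. This call was lost without knockdown replicate 6 or control replicate 6 (adjusted p = 0.0562 and 0.0642), with array weights, with a stricter filter and under quantile normalization. The interferon list gave no evidence of a shift (adjusted p = 0.997), with 7 of 45 that rose and 9 that fell (7 and 6 adjusted over the list alone). Its median was 0.08 and its mean 0.05, while camera ranked it lower. IFITM1, a membrane restriction factor, changed by -0.63, and the interferon-induced genes ISG20, IFI27 and MX1 rose by 0.95, 1.04 and 0.70, of which MX1 lay in a shifted window.

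The other aldehyde dehydrogenases did not move as a group (adjusted p = 0.245). Of 14 tested, 5 rose and 2 fell, also when adjusted over the list alone. ALDH3A1, which clears lipid and aromatic aldehydes (chromosome 17, 19641297 to 19652257), rose from 3.28 ± 0.684 to 10.7 ± 0.647 RPM, a log2 fold change of 1.73 (SE 0.153, adjusted p = 2.41e-09). ALDH3B1, of the same subfamily, rose by 1.08 and ALDH5A1, the succinic semialdehyde dehydrogenase, by 0.45, a call lost without a variance trend. ALDH6A1, of valine breakdown, changed by -0.32. ALDH7A1, ALDH3A2 and ALDH18A1 passed with changes of 0.23, 0.24 and -0.21. ALDH7A1 and ALDH3A2 lost their calls without control replicate 6 (0.11 and 0.10) and without any single knockdown replicate, and ALDH18A1 without knockdown replicate 4 or 5 or control replicate 4 or 5 (-0.21 to -0.17). The closest mitochondrial relative ALDH2 had 28.9 ± 4.28 and 33.8 ± 3.66 RPM and did not pass. It passed without control replicate 5 (log2 fold change 0.33) and under 5 other alternatives. ALDH1A3, the main retinal dehydrogenase expressed in these samples, had 183.7 ± 31.02 and 190.3 ± 15.3 and did not pass. Retinoid genes had 7 of 18 members that rose and 1 that fell (8 and 2 adjusted over the list alone, adjusted p = 0.0882). The retinoid-induced chemoattractant RARRES2 rose by 1.82, the retinol transporter STRA6 by 0.62, and the enzymes RDH14 and RETSAT by 0.65 and 0.52, all but STRA6 in shifted windows. Of 17 other alcohol and aldehyde clearance genes, 5 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.566). The glutathione transferases GSTK1, in a shifted window, and MGST1 changed by 0.97 and -0.74, the formaldehyde-clearing dehydrogenase ADH5 by -0.37, a call lost with window medians removed, and the aldo-keto reductase AKR1C2 by 0.73.

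Pathways of colon cancer cells outside the called lists had changed genes in both directions. Among 32 Wnt/beta-catenin targets 11 rose and 9 fell (14 and 10 adjusted over the list alone, adjusted p = 0.826). The adhesion molecule L1CAM rose by 0.97 and the ephrin receptor EPHB3 by 1.05, while BMP4 and the Wnt antagonist DKK1 changed by -0.79 and -1.43. In the Notch list 7 of 24 rose and 6 fell (7 and 7 adjusted over the list alone, adjusted p = 0.9002). The Notch target HES1 rose from 49.3 ± 9.85 to 157.4 ± 3.75 RPM, a log2 fold change of 1.70, while the ligand JAG1, the co-activator MAML1 and HES7 changed by -0.83, -0.55 and -0.96. Of 14 stem cell markers, 4 rose and 6 fell (5 and 7 adjusted over the list alone, adjusted p = 0.466), with SOX2 and KLF4 among the falls and EPCAM and the chemokine receptor CXCR4, with 0.86, among the rises. Drug transport and metabolism genes had 8 of 19 that rose and 5 that fell, also when adjusted over the list alone (adjusted p = 0.666). The efflux pump ABCB1 changed by -1.19, whereas the pump ABCC3 rose by 1.09, the oxidase CYP3A5 by 1.2525 and the sulfotransferase SULT1A1 by 0.96.

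The lists for DNA repair, apoptosis, NRF2 targets and the ATF4 response did not pass. DNA repair had 6 of 40 that rose and 6 that fell, also when adjusted over the list alone (adjusted p = 0.810), with a median of -0.04 and a mean of 0.003. Its 3 smallest p belonged to the Fanconi gene FANCD2, the recombination gene XRCC2 and the mismatch repair gene MSH6, which rose by 0.92, 0.52 and 0.36, all in shifted windows. Apoptosis genes had 7 of 35 that rose and 8 that fell, also when adjusted over the list alone (adjusted p = 0.649). The death activator BCL2L11, in a shifted window, rose by 0.71 and the caspase-8 inhibitor CFLAR by 0.47, while the effectors BOK and BAK1 changed by -0.58 and -0.63. NRF2 targets had 4 of 38 that rose and 11 that fell, also when adjusted over the list alone (adjusted p = 0.0835), with ABCC3 up and the autophagy receptor SQSTM1, the ferritin chain FTL and the peroxidase PRDX6 changed by -0.58, -0.54 and -0.43. The ATF4 list had 9 of 43 that rose and 14 that fell (10 and 14 adjusted over the list alone, adjusted p = 0.170), with the lipoprotein receptor VLDLR, the pseudokinase TRIB3 and the tRNA synthetases AARS and WARS changed by -0.93, -0.80, -0.56 and -0.54.

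Metabolic lists outside the mitochondrion did not pass either. Glycolysis and hypoxia genes had 15 of 40 that rose and 11 that fell (15 and 12 adjusted over the list alone, adjusted p = 0.788). The HIF targets KDM3A and PFKFB4, both in shifted windows, rose by 0.76 and 1.02, and EGLN3, the prolyl hydroxylase that limits HIF, by 0.96. The carbonic anhydrase CA9, another HIF target, rose from 0.0908 ± 0.0449 to 1.523 ± 0.320 RPM (adjusted p = 1.8e-06), but its control values are those of at most 3 reads per sample, so the size of its fold depends on the offset. Of 26 cholesterol genes 4 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.826). The thiolase ACAT2 changed by -0.31, and the enzymes HSD17B7 and MVD by 0.48 and 0.33, of which the first lost its call under quantile normalization and the second with GC trends removed. Fatty acid genes had 6 of 24 that rose and 6 that fell (7 and 7 adjusted over the list alone, adjusted p = 0.826), a median of -0.05 and a mean of 0.03. ACACB, the acetyl-CoA carboxylase of the mitochondrial surface, rose by 0.68, the acyl-CoA synthetase ACSL5 by 0.58 and the lipin LPIN1, in a shifted window, by 0.50, while the elongase ELOVL5 changed by -0.35. Folate and serine genes had 4 of 26 that rose and 8 that fell (5 and 9 adjusted over the list alone, adjusted p = 0.299). The purine enzyme ATIC and the folate carrier SLC25A32 changed by -0.53 and -0.56, and AMT of glycine cleavage, in a shifted window, rose by 1.44.

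Lists that follow RNA handling or other cells were mostly small or near the floor. Of 13 RNA interference genes 1 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.245), with AGO4 changed by 0.69 and the slicer AGO2 by -0.56. The 8 tested small RNAs had 3 that fell and 0 that rose (4 and 0 adjusted over the list alone, adjusted p = 0.170), and RN7SL2, their most abundant member that fell, had 145.7 ± 147.3 RPM in the control, a spread as wide as its mean, and lost its call without control replicate 6 (-0.54) or knockdown replicate 6 (-0.59) and under most rescalings. Nuclear long non-coding RNA had 3 of 20 that rose and 5 that fell, also when adjusted over the list alone (adjusted p = 0.461), with NORAD, listed as LINC00657, changed by -0.56. Of fibroblast markers 2 were tested and 1 rose (FBLN1, by 1.03), of leukocyte markers 3 were tested, of which LAPTM5 and CORO1A rose by 2.32 and 0.65 and CD68 changed by -1.93, and the 1 tested endothelial or blood marker did not pass. These counts were the same when adjusted over the list alone, and the lists were too short for camera. Of 5 markers of kidney, liver and breast lines 3 rose and 0 fell (3 and 2 adjusted over the list alone, adjusted p = 0.245). The keratin KRT5, at 2581 ± 132 RPM in the control, rose by 0.28, a call lost without knockdown replicate 6 (0.23) or control replicate 6 (0.24), the antiprotease SERPINA1 rose by 0.76, and the kidney transcription factor PAX8, in a shifted window, by 1.01.

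Changes were also grouped by position. There were 291 windows of 10 Mb with at least 10 tested genes. Not all of these could be chosen, since a choice needed at least 10 genes among every second gene. The 38 windows chosen as higher held 1818 genes (11.8% of those placed). Among genes held out from that choice, 85.0% of 906 lay above the median of all placed genes, against 44.9% of 6823 elsewhere. The longest stretch was on chromosome 2 from 0 to 130 Mb, where the held-out genes had a median log2 fold change of 0.49. On chromosome 3 the first 20 Mb had 0.71 and 30 to 70 Mb had 0.28, on chromosome 7 the last stretch, 120 to 160 Mb, had 0.45, on chromosome 13 110 to 120 Mb had 0.64, and on chromosome 21 30 to 50 Mb had 0.38. Windows chosen on chromosomes 9, 10 and X held weakly, with 57.1% to 71.4% of held-out genes above the median. The shifted windows contained 31.6% of the placed genes that rose. In these windows 60.8% of genes rose and 3.52% fell, against 17.5% and 21.3% elsewhere. Unlike the held-out values, these shares include the genes on which the windows were chosen, so part of the contrast was set by that choice. When the median deviation of each window was removed, BCL2L11, EDEM1, MRPS25, NDUFB2, RDH14 and RPS7 no longer passed, and RETSAT, RRM2, MSH6, SUCLG1, RPL32, PDIA4 and LPIN1 changed sign.

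**Figure D4:**
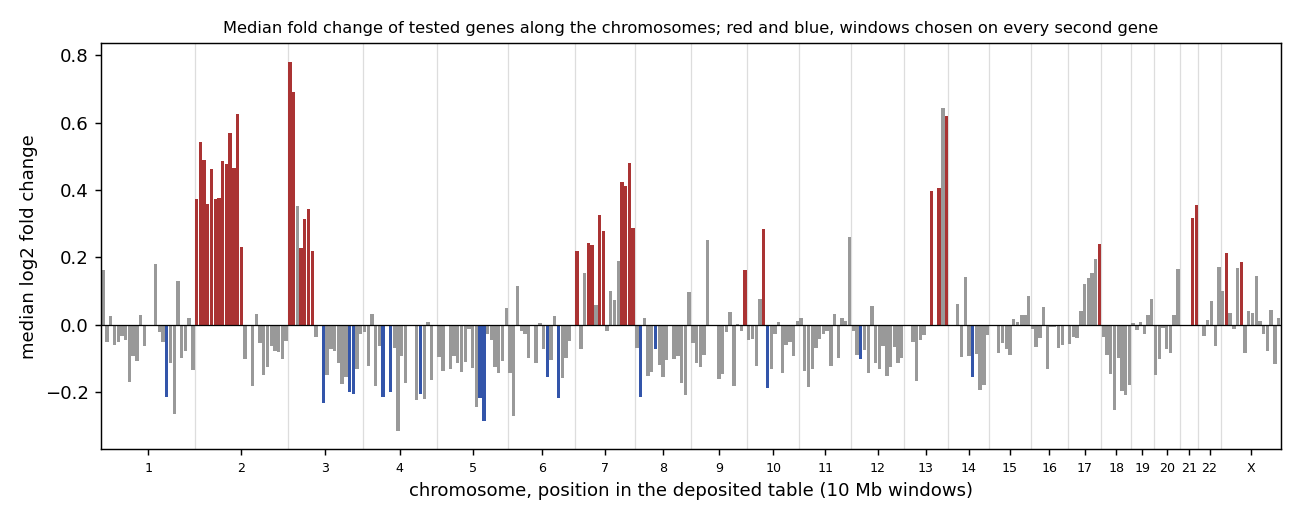
Median log2 fold change of tested genes in windows of 10 Mb along chromosomes 1 to 22 and X, in the coordinates of the deposited table. Red bars are the 38 windows chosen as higher on every second gene, most of them on chromosomes 2, 3, 7, 13 and 21, and blue bars the 16 chosen as lower.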

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

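The alternatives chosen only after the data were seen were a pseudocount of 0.688 RPM, removal of GC trends, removal of window medians, rescaling to nuclear protein-coding totals and leaving out the genes of the shifted windows. Trimmed-mean rescaling and count models were not run.

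ALDH1B1 kept its direction and its call under all 22 alternatives, with log2 fold changes of -0.86 to -0.71, and -0.86 to -0.74 when single samples were left out. The 24 genes named for the largest changes also kept direction and call under every alternative that gave them a value. They were picked for large changes without overlap in these same samples, so this was likely from the outset. The number of changed genes was 4929 to 6795 with a sample left out, against 6480, with 2904 to 3455 that rose and 2025 to 3738 that fell. It was 5481 with the replicate block and 5191 (2358 higher, 2833 lower) without the genes of the shifted windows. At the deposited scaling rises outnumbered falls in those windows, where 1106 placed genes rose and 64 fell, but not elsewhere, with 2389 and 2904. These counts include the genes on which the windows were chosen as higher, so part of the contrast was set by that choice. With window medians removed there were 3407 higher and 3312 lower, a near-even balance that centring each window tends to produce. The balance of rises and falls over all genes also changed with the scaling. Falls also outnumbered rises with median-of-ratios rescaling (3683 higher, 4075 lower), quantile normalization (3420 and 3890), array weights (3536 and 4105), GC trends removed (3549 and 3903), a mean of at least 3.44 RPM (2729 and 2823) and without control replicate 6 (3057 and 3738), while nuclear protein-coding totals gave 4569 higher and 2867 lower. At an adjusted p of 0.01 the genes that fell numbered 1942, and against a fold of 1.5 treat called 572, of which 433 rose and 139 fell; these stricter settings call fewer genes by construction. Over the rescalings, quantile normalization and GC correction, the median log2 fold change of all genes was -0.0429 to 0.0547, and 46.79% to 61.44% of the changed genes were higher.

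The gap between the lowest correlation within and the highest between groups was 0.0173. It was 0.0154, 0.0128 and 0.0106 with pseudocounts of 0.0688, 0.688 and 3.44 RPM, 0.022 with a mean of at least 3.44 RPM, 0.0148 with window medians removed, 0.0156 without the genes of the shifted windows and 0.0173 to 0.0197 with a sample left out. Without a filter it was -0.0125, where genes at the floor enter. The 11 called lists became 0 with an estimated correlation and 5 with fry, and 9 to 14 with a sample left out. MYC targets and ribosome biogenesis, heat shock, the mitochondrial ribosome, mitochondrially encoded genes and TGF-beta and YAP targets lost their calls only with an estimated correlation.

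Most reversals concerned values near 0, mitochondrial transcripts and genes in shifted windows, and the cause was not tested unless stated. The list of kidney, liver and breast markers was an exception, with a median of 0.2808 that became -0.3526 without a filter. Without a filter the medians were also -0.058 for Wnt and -0.015 for drug transport. At a mean of at least 3.44 RPM Wnt had -0.028. Median-of-ratios rescaling gave -0.0054 for drug transport. Quantile normalization gave -0.046 for ALDH1L1, 0 for MT-CO1, -0.031 for MT-ND5, 0.0196 for fatty acid synthesis and -0.0017 for interferon; it sets the most abundant transcripts of each sample to equal values. Array weights gave -0.058 for ALDH1A3, -0.0091 for glycolysis and -0.0175 for drug transport. Removal of GC trends gave -0.10 for ALDH16A1, -0.0052 for Wnt and -0.0306 for drug transport. Nuclear protein-coding totals gave 0.019 for DNA repair, 0.0086 for the unfolded protein response, 0.0064 for fatty acid synthesis, 0.0133 for apoptosis and 0.0153 for nuclear long non-coding RNA. Removal of window medians, which subtracts the shift of neighbouring genes, gave -0.0328 for RETSAT, -0.0703 for RRM2, -0.11 for MSH6, -0.12 for SUCLG1, -0.12 for RPL32, -0.0601 for PDIA4, -0.0691 for LPIN1, -0.0409 for ALDH1A3, -0.0055 for interferon, -0.0178 for drug transport and 0.0143 for nuclear long non-coding RNA. Without the genes of the shifted windows Wnt had -0.0285 and glycolysis -0.0703. With a sample left out, values ran from -0.0863 to 0.138 for ALDH1A3, -0.0171 to 0.259 for ALDH1L1, -0.0222 to 0.0903 for glycolysis, -0.136 to 0.0047 for fatty acid synthesis, -0.0188 to 0.113 for interferon and -0.0448 to 0.144 for drug transport, with the low ends without control replicate 6.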

Other observations

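The tests chosen only after the results were seen were those of copy number, of scatter over the genome, of mitochondrial RNA of every kind, of matched random lists, of list medians with window medians removed and of gene families by symbol. The tests of GC content, of rescaled totals and of other splits were written down before their results.

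Genes of some chromosome segments were higher together in the knockdown. A difference in copy number between the knockdown and control cells, such as arises when a subline is grown out, is a candidate explanation. It requires that genes not used to choose the segments be higher whatever their expression level, and 85.0% of the held-out genes were above the median. Their median exceeded that of genes elsewhere by 0.45, 0.45 and 0.38 for low, middle and high expression. The difference was alike in the libraries, 0.21 to 0.22 in each knockdown sample and -0.22 to -0.20 in each control sample, as deviations from the gene mean. Changes scattered without regard to position are argued against by an SD of window medians of 0.19, where the highest of 1000 shuffles gave 0.098. GC content is argued against as the cause, since the difference of medians over genes with a GC value was 0.42 before and 0.43 after each library's GC trend was removed. The 16 windows chosen as lower held less well, with 67.1% of held-out genes below the median. No DNA was measured, and a chromatin change over whole chromosome arms was not tested. The knockdown group may therefore differ from the control in more than ALDH1B1, and for genes such as EPCAM, TGFA, FANCD2 and MSH6 the knockdown and the segment are confounded. The 5 rises among the 24 most changed genes that lay in these windows had log2 fold changes of 2.43 or more (GRIP2 the smallest), against medians of 0.49 and 0.71 in their segments. They were named for their large rises, so an excess over those medians was set by the naming rule. ALK kept a log2 fold change of at least 1.61 under every alternative that gave it a value.

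The 13 mitochondrial mRNAs were higher. Different amounts of ribosomal RNA or mitochondrial reads in the totals are argued against as the whole cause, because the median log2 fold change went from 0.84 to 0.89 when the columns were rescaled to the same nuclear protein-coding total, and all 13 still passed. More mitochondrial RNA of every kind would raise MT-RNR2 as well, and its log2 fold change was -0.23. MT-RNR2 was steady among control samples (8520 ± 236.4 RPM, SD, n = 3) and lower in every knockdown sample (7267 ± 464.3), which goes against that explanation if ribosomal RNA was measured as the mRNAs were. That is not established. MT-RNR1, from the same precursor, varied by 1.47 log2 units among control samples alone, whether ribosomal RNA was removed is not given, and a removal that differed between the groups was not tested. The explanation therefore stays undecided. A higher steady state of mitochondrial mRNA together with lower nuclear genes for the mitochondrial ribosome remains a hypothesis, and no test here separates it from RNA handling.

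Lists for ribosome biogenesis, heat shock, the mitochondrial ribosome and DNA replication fell at the preset correlation. Each of these calls was lost with an estimated correlation (adjusted p = 0.9884), and that of DNA replication also with fry (adjusted p = 0.1463). Fold changes across tested genes followed expression level (Spearman rho -0.25) and GC content (rho 0.16), where genes are not independent replicates. Against 10000 random lists matched on both, the medians of ribosome biogenesis, heat shock and the mitochondrial ribosome lay at percentile 0, which argues against these trends as their cause. The DNA replication list lay at percentile 6.03, so its fall is consistent with the trend alone. Beyond these 4 lists, mesenchymal genes lay at percentile 10.98, nuclear-encoded oxidative phosphorylation at 39.7 and histones at 83.3, inside the range of matched lists. Outside it, TGF-beta and YAP targets lay at 0.16, NF-kB and cytokines at 98.51, and MAPK and immediate early genes at 100. Some lists that camera did not call also lay outside the range. Small nucleolar and small nuclear RNA lay at 0, epithelial genes at 98.9, and extracellular matrix and integrins at 99.96. A place outside the range was therefore not limited to called lists. Shifts of whole chromosome segments, higher or lower, are argued against as the whole source of the falls, because with window medians removed the medians of the 4 lists still lay below that of all genes (smallest gap -0.1391, for DNA replication) and camera at the preset correlation still called each. A lower drive from MYC, whose own transcript had a log2 fold change of -0.47, is a hypothesis for part of the pattern, and slower growth is an alternative. These samples test neither.

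Of the 10 splits of the 6 samples into 3 and 3, only 1, the real split, gave as many changed genes, 6480, and the highest of the other splits gave 0. In limma those 9 splits had 46 to 650 genes at an unadjusted p under 0.05, and the real split 7627. Each of those 9 splits mixes knockdown and control samples, so the difference between the groups adds to their spread and made calls unlikely from the outset. With 10 splits the share cannot fall under 0.1, so this count is too small to decide on chance.

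Gene families formed by symbol, 168 with at least 10 tested members, were tested beside the written lists and partly overlap with them. MRPL and HIST share genes with the mitochondrial ribosome and histone lists. Families were not compared with random lists matched on expression and GC content, so the trends of the fold change with both were not separated from their calls. A family holds every gene whose symbol has the same letters before its first digit, so it can include pseudogenes, antisense transcripts and binding proteins. By camera at the preset correlation 12 families passed, 5 higher and 7 lower, and with an estimated correlation 0 passed (2 at an unadjusted p under 0.05, adjusted p = 0.9958 for each of the 12). The lower families were EIF (35 of 68 that fell and 5 that rose, adjusted p = 4.5e-05), MRPL (24 of 50 and 4), NPM (8 of 11 and 0), TIMM (10 of 14 and 1), PSMD (9 of 17 and 1), PSMB (6 of 10 and 0) and POLR (12 of 31 and 2). The higher families were MIR (11 of 21 that rose and 0 that fell), LINC (34 of 91 and 4), HIST (13 of 35 and 2), ITGB (7 of 12 and 1) and COL (10 of 20 and 1). Of the ITGB genes 3 lay in shifted windows, of the COL genes 6 and of the LINC genes 18.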
